A study of Mus musculus with 10 samples.

How the data were processed

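Total RNA of dorsal root ganglia was sequenced in 10 mouse samples, 5 after oxaliplatin and 5 after vehicle, grouped by the labels' titles and treatment field. Per the labels' protocols, tissue was kept in RNAlater, RNA was extracted on magnetic beads and libraries were made with a SMARTer kit; whether the libraries kept strand is not stated there. The labels number the libraries within each group and do not say in words that each came from a different animal, so the p-values measure the spread between these samples. The dosing schedule behind 10 mg/kg is not given in the sources used here.

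The deposited table holds raw read counts per Ensembl gene, with 1 column for each of the 10 samples, and the values are whole numbers. Per the submitters' processing notes, STAR 2.5.1a, Partek and DESeq2 were used, with no role named for each; the genome build, the annotation release and the counting step are not given in the sources used here, so no coordinates are printed. The table has 40757 rows for 40481 distinct Ensembl IDs: 167 IDs are listed more than once with identical counts, and the 276 extra rows were dropped. Gene symbols stored as dates (26) were restored by ID. Of the IDs, 40254 are also in the GENCODE M21 name table. The deposited table stops at an ID after which the name table lists 15196 more genes, 91.9% of them with predicted or clone names; these are not analysed here. Genes that overlap or share reads with a near-identical copy, such as histones and MHC genes, carry an uncertainty that the counting step would decide, and sense and antisense partners cannot be told apart without a statement on strand.

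Library totals ran from 52963470 to 60984426 counts, the mitochondrial share from 1.34 to 1.76% and the share of Gm42418, a transcript that overlaps ribosomal RNA, from 0.856 to 1.25%. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 12.7 to 53.5), so none was merged as a repeat run of another. Each counted as 1 replicate, but this check cannot show that they came from different animals. The biological coefficient of variation was 19.3%.

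Differences were tested with edgeR 4.0.16 under R 4.3.3: genes kept by filterByExpr, TMM factors, robust quasi-likelihood fits without covariates and Benjamini-Hochberg adjustment over all tested genes, with a threshold of 0.05. SE values of single genes are the log2 fold change divided by the root of the F statistic. Those of list medians come from resampling the genes of a list, and that of the clock gene sets from the spread between genes. Neither of these measures the spread between animals. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. Gene lists (47, for pathways, cell types and RNA quality) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and their members were counted by the edgeR test over all genes and adjusted over the list alone. Txnip was also tested alone with an exact permutation test. Genes to be named were fixed by a rule: Txnip; the 12 largest changes in each direction among genes past the threshold with a mean of at least 2 CPM, groups without overlap and no predicted or clone name; and up to 4 members of smallest p per list. Nlrp3, Il1b, Arrdc4, Ckm, Gal and the genes of the added lists were named after their values were seen. Members that the rule gave are described as examples, not all of them, and 1 result is not reported here. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

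The gene test was tested on simulated counts for 18130 genes of the oxaliplatin and vehicle comparison. It recovered 68% of 50 genes changed 1.5-fold, 94% of 50 changed 2-fold, 98% of 50 changed 4-fold and 94% of 50 changed 0.5-fold. These changed genes were drawn from those with a mean of at least 2 CPM. Of 194 calls 14 (7.22%) were false, and 0 of 40 null lists were called. Genes were simulated without correlation between them, while the real lists had estimated correlations of up to 0.78. The 0 of 40 therefore does not give the error rate of camera on the real lists.

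The alternatives were DESeq2's size factors or no composition factor in the edgeR test, no filter or a stricter filter on low counts (1 CPM in 5 libraries), DESeq2 1.42.0, limma voom with quality weights, the replicate number as a block, 1 surrogate variable from sva 3.50.0, the mean of the Schwann cell list as a covariate, an adjusted p threshold of 0.1, and leaving out each library in turn; for lists also fry and an estimated correlation. Chosen after seeing the data were 7 more gene lists and the fit without both oxaliplatin replicate 1 and vehicle replicate 5.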

Results

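Gene expression was measured by RNA sequencing in dorsal root ganglia (DRG), the clusters of sensory neuron cell bodies beside the spinal cord, of C57BL/6 mice. The series holds 1 comparison, between 5 libraries from mice given oxaliplatin, a platinum drug used against colorectal cancer that damages sensory nerves, and 5 libraries from mice given vehicle. The labels give a dose of 10 mg/kg and the design text a treatment of 8 weeks. Each library held 52963470 to 60984426 counted reads. Enough counts to be tested were found for 18401 genes. The counts per library of Xist (0 to 10) and of the Y-linked gene Ddx3y (1767 to 2678) were those of male animals in all 10 libraries.

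The series title names the TXNIP pathway, so the first question was whether Txnip (ENSMUSG00000038393), which codes for a protein that binds and inhibits thioredoxin, differed after the drug. Txnip had a level of 85.2 ± 30 CPM (counts scaled to library size, mean ± SD, n = 5) after oxaliplatin and 38.7 ± 6.60 CPM after vehicle (n = 5). The log2 fold change was 1.14 ± 0.27 (SE), or 2.20-fold. It did not pass the threshold over all genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0785). The 4 oxaliplatin libraries other than replicate 2 lay above every vehicle library, and replicate 2, at 41.3 CPM, lay within the vehicle range. Tested alone, the difference in mean log2 CPM was 1.07 (two-sided exact permutation test, p = 0.0238, with 0.00794 the smallest p that 252 splits allow). That p is not adjusted over all genes. The gene was taken from the title of this same series, so its choice may not be independent of these counts. The call depended on the library and the tool. Without oxaliplatin replicate 2 the log2 fold change was 1.31 (edgeR adjusted p = 0.00201), and the adjusted p was 0.00236 in DESeq2 and 0.0109 in limma voom with quality weights. Over all alternatives it ranged from 0.00201 to 0.259.

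Around Txnip, the list of the thioredoxin system and the NLRP3 inflammasome did not pass the list test. Of its 12 tested members 0 rose and 1, Txn1, the thioredoxin that Txnip binds, fell by 0.22 ± 0.05 on the log2 scale (edgeR adjusted p = 0.0438, up to 0.126 when 1 library was left out and past the threshold in 2 of 10 such fits). Adjusted over the list alone, 1 was higher (Txnip) and 3 were lower. The list test gave an adjusted p of 0.491 (camera), with a mean above 0 and a test direction below it. Casp1, the inflammasome protease, was at -0.38 ± 0.12 (edgeR adjusted p = 0.110). Nlrp3, the inflammasome sensor, and Il1b, its cytokine product, were named after their values were seen. Nlrp3 had 0 to 2 counts per library after oxaliplatin and 2 to 10 after vehicle, and Il1b 0 to 6 and 9 to 26, below the filter on low counts. Without that filter Nlrp3 was at -2.12 ± 1.11 and Il1b at -2.51 ± 0.78 (edgeR adjusted p = 0.411 and 0.109). Arrdc4, like Txnip an alpha-arrestin switched on by the sugar sensor MondoA, and also named after its value was seen, was at 0.23 ± 0.33 (edgeR adjusted p = 0.802). None of the 9 tested members of the MondoA and ChREBP list passed over all genes, and 1 was lower adjusted over the list alone. The camera adjusted p was 0.491, again with a mean above 0 and a test direction below it.

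**Figure D1:**
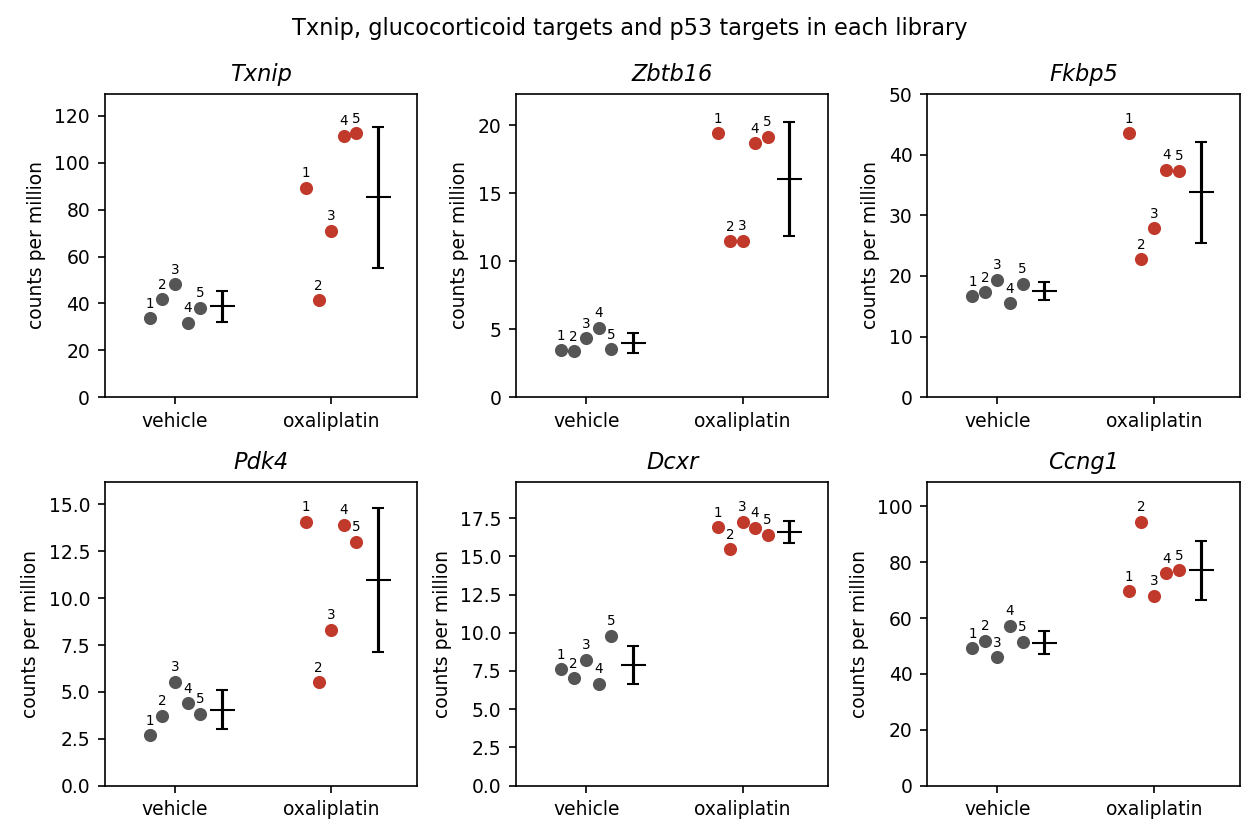
CPM of 6 genes in each library (numbered points), with the mean and SD (n = 5) to the right of each group, on axes that start at 0. Txnip lies above all vehicle libraries in 4 of 5 oxaliplatin libraries, and Dcxr (16.6 ± 0.693 against 7.87 ± 1.23 CPM) in all 5.

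Over all genes, 234 were higher and 142 lower after oxaliplatin (edgeR quasi-likelihood test, adjusted p below 0.05). Of these, 68 rose and 23 fell by at least 2-fold. The libraries of the groups did not overlap for 739 tested genes, 4.02% of those tested, where chance gives 0.794%. Among the genes with the largest change that meet the naming rule, Plin4, a coat protein of lipid droplets, rose 10.4-fold (log2 fold change 3.38 ± 0.64) and Etnppl, an enzyme of phospholipid breakdown, 5.08-fold. Zbtb16, a transcription factor that glucocorticoids induce, rose 4.05-fold (from 3.96 ± 0.745 to 16.0 ± 4.18 CPM, n = 5 and 5). Gtse1, a cell cycle gene that p53 switches on, rose 3.44-fold, and Adm, the vessel-dilating peptide adrenomedullin, 3.16-fold. The other 7 were Wfdc17 (3.34-fold), the matrix genes Ccn5 (3.06-fold) and Aspn (2.46-fold), the adrenergic receptor Adra2b (3.03-fold), Fam107a (2.76-fold), the respiratory chain subunit Cox4i2 (2.36-fold) and Kcnj8 (2.34-fold), a potassium channel of pericytes. Zbtb16, Gtse1, Adm, Ccn5, Fam107a, Aspn, Cox4i2 and Kcnj8 kept their calls whichever library was left out. Plin4, Etnppl, Wfdc17 and Adra2b lost theirs in 9, 1, 5 and 6 of 10 such fits (highest edgeR adjusted p 0.107, 0.0544, 0.0681 and 0.0798), Etnppl without vehicle replicate 4. A count moved by over 1.5 times without oxaliplatin replicate 1 (147 higher and 74 lower), replicate 2 (343 and 251), replicate 4 (79 and 34) or replicate 5 (80 and 38). The same held without vehicle replicate 1 (117 and 77), replicate 4 (82 and 41) or replicate 5 (198 and 88), and without both oxaliplatin replicate 1 and vehicle replicate 5 (142 and 76), a fit chosen after seeing the data. Of 68 called genes named in the text, 45, 63, 52, 35 and 39 kept their calls without oxaliplatin replicates 1 to 5, and 46, 59, 55, 36 and 53 without vehicle replicates 1 to 5. The share of calls that were higher was 62.2%. It was 75.4% (303 and 99 genes) without a composition factor and 50.7% (423 and 412) with the Schwann cell level as a covariate.

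Targets of p53, which responds to DNA damage, rose as a group. Of 31 tested members 10 were higher and 0 lower, and 18 were higher and 1 lower adjusted over the list alone, at a median log2 fold change of 0.42. Dcxr rose 2.11-fold (1.08 ± 0.11), Gtse1 3.44-fold, the growth restraint gene Sesn1 1.56-fold (0.64 ± 0.08) and Ccng1 1.51-fold (0.59 ± 0.09), with every oxaliplatin library above every vehicle library for each. All 4 kept their calls whichever library was left out. The list lay above other genes (camera adjusted p = 5.51e-16). Of the 23 lists called by camera it was the only 1 that also passed with an estimated correlation (adjusted p = 0.0137). Nucleotide excision and crosslink repair genes had 0 of 26 members past the threshold, over all genes or adjusted over the list alone, at a median of 0.11. Their camera adjusted p was 0.0191 (adjusted p = 0.194 with an estimated correlation) and 0.0518 without vehicle replicate 5. It lay just above 0.05 with 1 surrogate variable and was 0.0815 without vehicle replicate 5 and oxaliplatin replicate 1. Cell cycle genes had 4 of 30 higher (6 adjusted over the list alone), among them the mitotic genes Aurkb (1.97 ± 0.43) and Cdc20 (1.3 ± 0.29), which had means below 2 CPM. Their edgeR adjusted p rose to 0.0798 and 0.102 when 1 library was left out. The list lay above other genes (camera adjusted p = 1.13e-05, and adjusted p = 0.298 with an estimated correlation).

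Glucocorticoid targets rose more than any other pathway list in median (0.86). Of 19 tested members 8 were higher and 0 lower, and 17 were higher adjusted over the list alone (camera adjusted p = 1.60e-17, and adjusted p = 0.15 with an estimated correlation). Besides Zbtb16 and Plin4, Fkbp5, a chaperone that restrains the glucocorticoid receptor, rose 1.93-fold (0.95 ± 0.15) and Pdk4, which limits the use of glucose in mitochondria, 2.71-fold (1.44 ± 0.27). Cdkn1a, a cell cycle inhibitor that is also on the p53 list, rose 1.83-fold (0.88 ± 0.15). Fkbp5 kept its call whichever library was left out, and Pdk4 and Cdkn1a reached edgeR adjusted p values of 0.0679 and 0.0623 in such fits. Adipocyte RNA was high in 1 library of the same group, where Cfd, an adipocyte protease, stood at 457 CPM in oxaliplatin replicate 1 and at 3.91 to 29.3 CPM in the others. Of 11 tested adipocyte markers 1, Plin4, rose, also adjusted over the list alone (camera adjusted p = 0.0545). The adipocyte list passed without oxaliplatin replicate 2 (0.00661), 3 (0.0497), 4 (0.0182) or 5 (0.0269) or vehicle replicate 4 (0.0367), with RLE factors (0.048) and with the stricter filter (0.0259), and its camera adjusted p was 0.458 without oxaliplatin replicate 1. Among metallothioneins 0 of 4 passed over all genes and 2 were higher adjusted over the list alone, with Mt2 at 1.65 ± 0.42 (edgeR adjusted p = 0.0992) and a camera adjusted p of 0.1 (0.0413 without vehicle replicate 5, 0.0356 without that library and oxaliplatin replicate 1). Clock genes had 0 of 18 past the threshold (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.387).

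**Figure D2:**
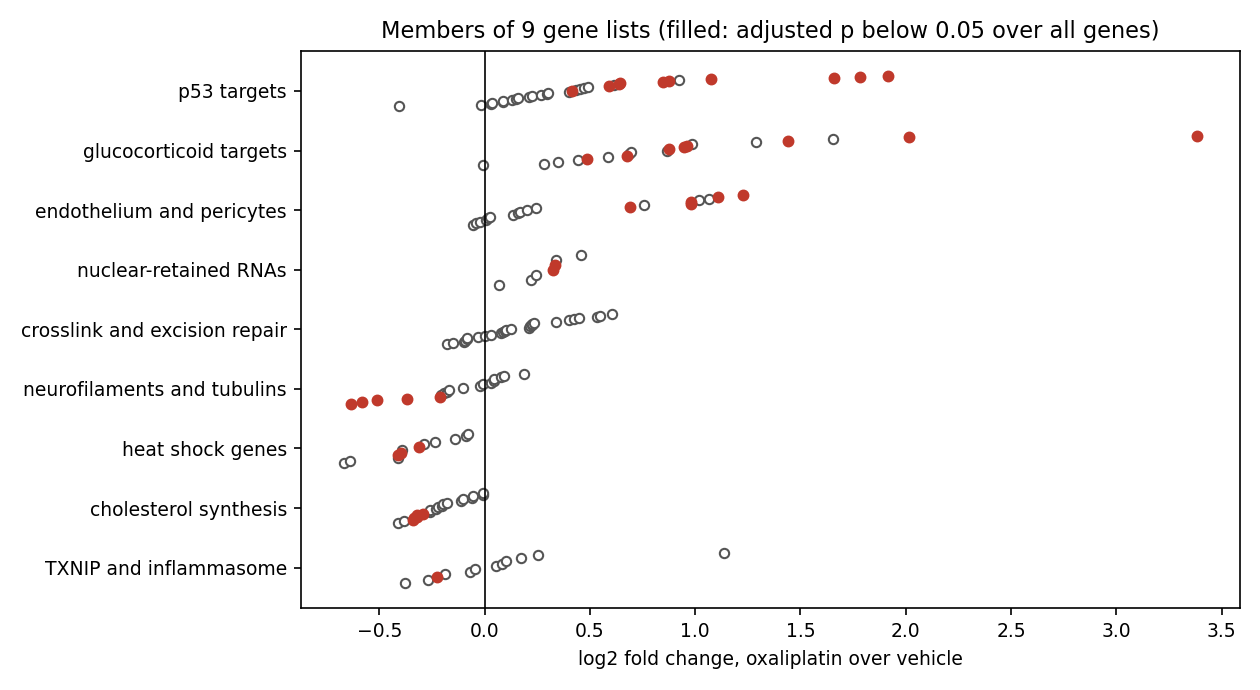
Log2 fold change of each tested member of 9 gene lists, oxaliplatin over vehicle, with 1 point per gene, filled where it passed the edgeR test over all genes. Filled points lie above 0 in the p53 and glucocorticoid lists, with 10 and 8 genes, and below 0 in the neurofilament, heat shock and cholesterol lists, with 5, 3 and 5.

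Among the genes that meet the naming rule, the 4 with the largest falls serve antigen presentation on MHC class II molecules. H2-Aa, H2-Ab1 and H2-Eb1, chains of those molecules, fell 4.52-fold, 4.24-fold and 3.50-fold, and Cd74, which escorts them, 4.28-fold (from 150 ± 35.8 to 35.1 ± 10.1 CPM, n = 5 and 5). Ly86, which pairs with a receptor of the Toll-like family on B cells and myeloid cells, fell 2.58-fold (-1.37 ± 0.12), from 155 ± 30.2 to 60.1 ± 6.06 CPM. Which cells of the ganglion made the Ly86 transcript was not measured. Each of these 5 genes was lower in all 5 oxaliplatin libraries than in any vehicle library and kept its call whichever library was left out. Also lower among the genes that meet the naming rule were Cx3cr1, the fractalkine receptor (3.32-fold), Cybb, the catalytic part of the phagocyte oxidase (1.77-fold), and the monocyte attractant Ccl2 (2.43-fold). Their edgeR adjusted p rose to 0.0581, 0.0668 and 0.0811 when 1 library was left out, for Cx3cr1 without oxaliplatin replicate 4 or 5. The naming rule also gave Rlbp1, which binds retinoids (2.0-fold lower), Hpgd, which breaks down prostaglandins (1.81-fold lower), and Slurp2 (1.87-fold lower), which reached edgeR adjusted p values of 0.0525 (without vehicle replicate 4), 0.0795 and 0.135 in such fits. Class II genes belong to a multigene family, and how the authors' counting treated reads that fit more than 1 member is not given in the sources used here.

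Macrophage markers had 0 of 18 tested members higher and 2 lower, Cx3cr1 and the protease Ctss (-0.73 ± 0.17, edgeR adjusted p = 0.0394, up to 0.12 when 1 library was left out). Lyve1 was higher and 7 were lower adjusted over the list alone, and over all genes Lyve1 was at 0.64 ± 0.16 (edgeR adjusted p = 0.0526). The list lay below other genes (camera adjusted p = 0.00501, and adjusted p = 0.495 with an estimated correlation). That camera value was 0.0581 without oxaliplatin replicate 2 and 0.0541 without vehicle replicate 5. It lay just above 0.05 with 1 surrogate variable and was 0.154 without vehicle replicate 5 and oxaliplatin replicate 1. Lymphocyte markers had 0 of 10 past the threshold and 1 lower adjusted over the list alone. Their camera adjusted p was 0.0241 (adjusted p = 0.371 with an estimated correlation) and 0.0524 without vehicle replicate 2. Neutrophil and monocyte markers had 0 of 14, and 0 adjusted over the list alone (camera adjusted p = 0.382, and 0.0283 without vehicle replicate 1). Among cytokines and chemokines 2 of 16 rose, the stromal chemokine Cxcl12 (0.59 ± 0.11) and the alarmin Il33 (0.58 ± 0.14), and 1, Ccl2, fell. A total of 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.706). Cxcl12 and Il33 reached edgeR adjusted p values of 0.0565 and 0.0806 when 1 library was left out, Cxcl12 past 0.05 without oxaliplatin replicate 4 or vehicle replicate 4. The 14 tested complement genes lay above other genes as a list (camera adjusted p = 0.00150, and adjusted p = 0.412 with an estimated correlation). Cfd, high in oxaliplatin replicate 1 alone, is on this list too, at 3.29 ± 1.26 (edgeR adjusted p = 0.247). Interferon-stimulated genes had 0 of 22 past the threshold, over all genes or adjusted over the list alone. Their camera adjusted p was 0.491, below 0 in direction while the median was 0.23. Without oxaliplatin replicate 2 it was 1.4e-07, on the lower side. The mean log2 CPM of this list was 4.67 in that library, 2.53 to 3.27 in the other oxaliplatin libraries and 3.09 to 3.56 after vehicle.

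Neurofilament transcripts, which code for the structural filaments of large axons, were lower. Nefl fell by 0.51 ± 0.07 on the log2 scale, from 4212 ± 228 to 2952 ± 352 CPM (n = 5 and 5), Nefm by 0.58 ± 0.09 and Nefh by 0.63 ± 0.13, with no overlap between the groups for any of them. Of 18 neurofilament and tubulin genes 5 fell and 0 rose, and 9 were lower adjusted over the list alone (camera adjusted p = 5.13e-05, and adjusted p = 0.15 with an estimated correlation). Nefl and Nefm kept their calls whichever library was left out, and Nefh reached an edgeR adjusted p of 0.0924. The lists chosen for RNA quality moved beside them, with nuclear-retained RNAs at a median of 0.32 (camera adjusted p = 1.84e-05) and replication-dependent histones at -0.30 (camera adjusted p = 0.0135). Neither passed 0.05 with an estimated correlation (adjusted p = 0.15 and 0.479). Whether RNA handling or the drug moved these lists was not tested. Genes that rise in sensory neurons after axon injury had 0 of 21 past the threshold over all genes and 6 lower adjusted over the list alone (camera adjusted p = 5.02e-06, and adjusted p = 0.479 with an estimated correlation), with Bdnf at -1.11 ± 0.31 (edgeR adjusted p = 0.121). Their mean was highest in vehicle replicate 5, where Sprr1a stood at 189 CPM against 0.137 to 11.6 CPM in the other 9 libraries. The list kept its call without that library (camera adjusted p = 4.58e-05). Immediate early genes had 0 of 19 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.0241, and adjusted p = 0.515 with an estimated correlation). Without vehicle replicate 5 their camera adjusted p was 0.124. They also lost the call without oxaliplatin replicate 1 (0.0608) or 3 (0.0613) and without vehicle replicate 4 (0.0952), with the stricter filter (0.0777), with 1 surrogate variable (0.267) and without both oxaliplatin replicate 1 and vehicle replicate 5 (0.351).

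Ion channels and neuron classes changed in few members. The potassium channel Kcnd1, which carries a transient current, fell by 0.41 ± 0.08 (edgeR adjusted p = 0.0134) and kept its call whichever library was left out. It was the only 1 of 35 potassium and HCN channel genes past the threshold, over all genes and adjusted over the list alone (camera adjusted p = 0.0723). As a list they passed, on the lower side, without oxaliplatin replicate 1 (0.0471) or 4 (0.031) or vehicle replicate 3 (0.0297) or 5 (0.0077), without oxaliplatin replicate 1 and vehicle replicate 5 together (0.00497), with 1 surrogate variable (0.00319) and with the stricter filter (0.049). Sodium channels had 0 of 13 (1 higher adjusted over the list alone, Scn3b at 0.37 ± 0.10, camera adjusted p = 0.110). They passed as a list, on the higher side, without oxaliplatin replicate 5 (0.0393) or vehicle replicate 1 (0.0412) or 2 (0.0152). Calcium channels had 0 of 15 (0 adjusted over the list alone, camera adjusted p = 0.147). Of 22 thermal and mechanical transducers 1, the ATP-gated channel P2rx3, fell (-0.31 ± 0.07, edgeR adjusted p = 0.0314, up to 0.111 when 1 library was left out). A total of 4 were lower adjusted over the list alone (camera adjusted p = 0.145). The cold sensor Trpm8 was at 0.36 ± 0.21 (edgeR adjusted p = 0.436). Peptidergic nociceptor markers had 1 of 11 lower, Smr2 (-0.74 ± 0.13), and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.255). Non-peptidergic markers had 1 of 16 lower, P2rx3, and 4 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.976, above 0 in direction while the median was below it). Mechanoreceptor markers had 1 of 13 lower, Nefh, and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.493). Cold-sensing neurons (0 of 4, camera adjusted p = 0.369) and proprioceptors (0 of 9, camera adjusted p = 0.685) had none past the threshold, over all genes or adjusted over the list alone.

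**Figure D3:**
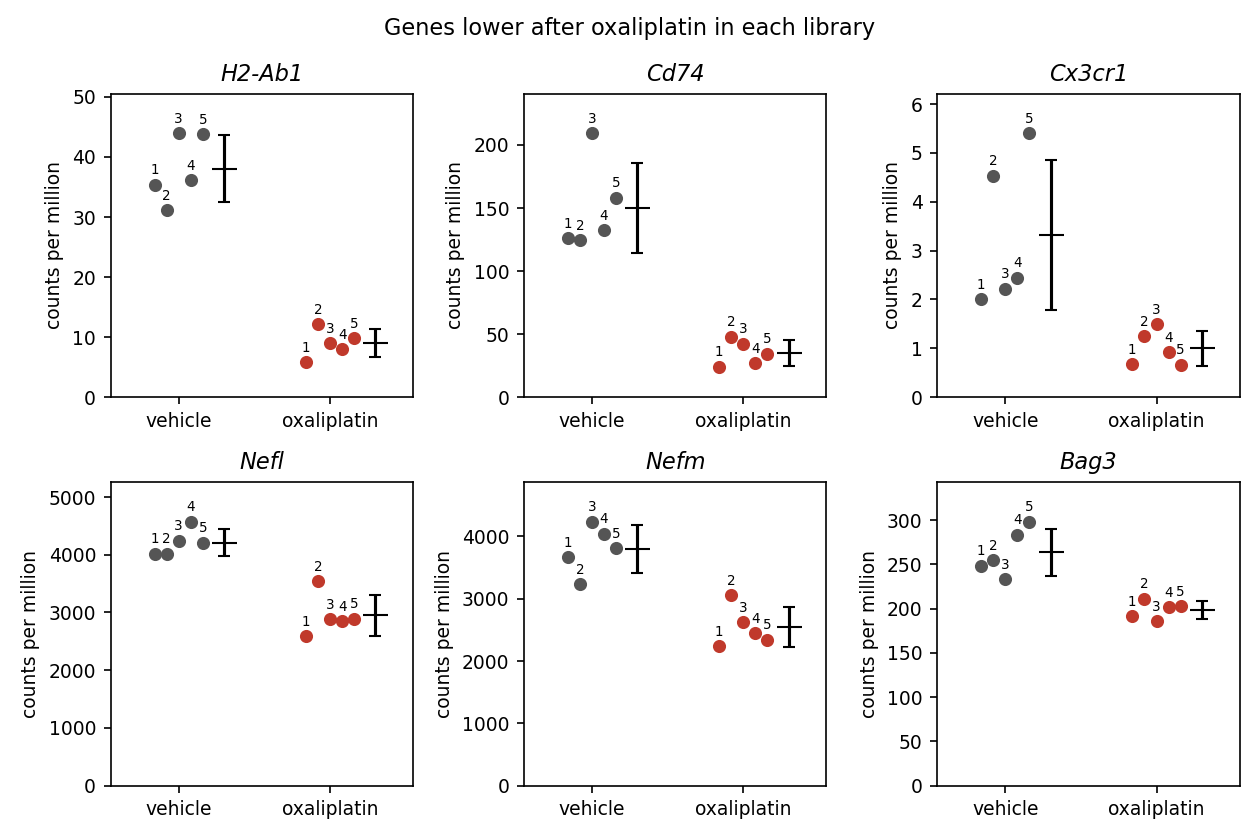
CPM of 6 genes that fell, in each library (numbered points), with the mean and SD (n = 5) to the right of each group, on axes that start at 0. All 5 oxaliplatin libraries lie below all 5 vehicle libraries in each of the 6 panels.

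Cholesterol synthesis genes were lower by small amounts. Of 20 tested members 5 fell and 0 rose, and 14 were lower adjusted over the list alone, at a median of -0.23 (camera adjusted p = 2.57e-11, and adjusted p = 0.15 with an estimated correlation). Nsdhl, a sterol dehydrogenase, fell by 0.32 ± 0.06 and Sqle, the squalene epoxidase, by 0.34 ± 0.07. Nsdhl kept its call whichever library was left out and Sqle reached an edgeR adjusted p of 0.0681. Heat shock genes had 3 of 12 lower, 0 higher and 9 lower adjusted over the list alone (camera adjusted p = 6.95e-09, and adjusted p = 0.15 with an estimated correlation). Bag3, a co-chaperone, fell by 0.41 ± 0.07 and kept its call whichever library was left out. Hspd1, the mitochondrial chaperonin, fell by 0.31 ± 0.07 (highest edgeR adjusted p 0.0841 in such fits). Respiratory chain genes coded in the nucleus had 1 of 75 lower, Atp5g1 (-0.27 ± 0.07, edgeR adjusted p = 0.0493, up to 0.139 when 1 library was left out). None was past it adjusted over the list alone (camera adjusted p = 1.19e-07, and adjusted p = 0.515 with an estimated correlation). Mitochondrial genome transcripts had 0 of 13 past the threshold, over all genes or adjusted over the list alone. Their camera adjusted p was 0.00966 (adjusted p = 0.515 with an estimated correlation) and 0.135 without vehicle replicate 3. Cytosolic ribosomal protein genes had 0 of 80, likewise 0 adjusted over the list alone (camera adjusted p = 0.00214, and adjusted p = 0.652 with an estimated correlation). This last list lost its camera call without oxaliplatin replicate 2 (0.0657), vehicle replicate 3 (0.380) or vehicle replicate 5 (0.437), with 1 surrogate variable (0.611) and without both oxaliplatin replicate 1 and vehicle replicate 5 (0.980). Beside these 3 lists, nuclear-retained RNAs were at a median of 0.32 (camera adjusted p = 1.84e-05, and adjusted p = 0.15 with an estimated correlation). The mean log2 CPM of skeletal muscle markers was -0.19 to 0.87 in 4 oxaliplatin libraries, 4.99 in replicate 1 and 2.04 to 4.24 after vehicle. Among antioxidant genes Gstm1, a glutathione transferase, rose by 0.45 ± 0.10 and Hmox1, haem oxygenase, fell by 0.31 ± 0.08, 1 of 23 each. Of the 23, 1 was higher and 2 were lower adjusted over the list alone (camera adjusted p = 0.0519). This list passed, on the lower side, without oxaliplatin replicate 1 (0.0398) or 5 (0.0228) or vehicle replicate 1 (0.0111), 2 (0.0152) or 4 (0.0427) and with RLE factors (0.048), and was at 0.308 without vehicle replicate 3. Gstm1 and Hmox1 lost their calls when 1 library was left out (highest edgeR adjusted p 0.0972 and 0.147). Genes of the integrated stress response and of endoplasmic reticulum stress had 0 of 21 (camera adjusted p = 0.0932) and platinum transporters 0 of 10 (camera adjusted p = 0.502, below 0 while the mean was above it), with 0 adjusted over the list alone in both. The stress response list passed, on the lower side, without oxaliplatin replicate 5 (0.0314) or vehicle replicate 1 (0.0489) or 3 (0.0314).

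Some genes of vessels and connective tissue rose. Of 19 endothelial and pericyte markers 5 rose and 0 fell, and 7 were higher adjusted over the list alone (camera adjusted p = 5.22e-06, and adjusted p = 0.15 with an estimated correlation). Kcnj8 rose 2.34-fold and Pecam1, an adhesion molecule of endothelium, 1.98-fold (0.98 ± 0.18, edgeR adjusted p = 0.0164, 0.0504 without oxaliplatin replicate 4). Of 23 matrix genes 3 rose, among them Fbn1, the microfibril protein fibrillin (0.85 ± 0.12), and Lox, which crosslinks collagen (1.20 ± 0.20), both of which kept their calls whichever library was left out. Adjusted over the list alone 10 were higher and 2 lower. The matrix list had a camera adjusted p of 0.0174 (adjusted p = 0.517 with an estimated correlation) and of 0.307 without oxaliplatin replicate 2. Fibroblast markers had 1 of 19 higher, Pdgfra (0.62 ± 0.14, edgeR adjusted p = 0.0266, up to 0.0858 when 1 library was left out). A total of 7 were higher adjusted over the list alone (camera adjusted p = 2.88e-04, and adjusted p = 0.455 with an estimated correlation). Among myelinating Schwann cell genes 2 of 16 rose, Cnp (0.46 ± 0.08) and Drp2 (0.47 ± 0.09), and 4 were higher adjusted over the list alone (camera adjusted p = 2.21e-04, and adjusted p = 0.479 with an estimated correlation). Non-myelinating Schwann cells had 1 of 10 higher, Art3 (0.45 ± 0.09, edgeR adjusted p = 0.0538 without oxaliplatin replicate 5). It was also the 1 gene higher adjusted over the list alone (camera adjusted p = 0.505, above 0 in direction with a median below it). In satellite glia, which wrap the neuron bodies, Glul, glutamine synthetase, rose by 0.38 ± 0.08 and Fabp7, a fatty acid carrier, fell 1.97-fold (-0.98 ± 0.18), 1 of 12 each. Adjusted over the list alone 3 were higher and 4 lower (camera adjusted p = 0.107, and 0.0496 without oxaliplatin replicate 3). The edgeR adjusted p of Glul and Fabp7 reached 0.0733 and 0.0779 when 1 library was left out.

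Markers of neighbouring tissue and genes chosen for RNA quality were tested as lists too. Skeletal muscle markers had 0 of 16 past the threshold, over all genes or adjusted over the list alone, at a median of -0.76 (camera adjusted p = 3.82e-09, and adjusted p = 0.371 with an estimated correlation). The muscle creatine kinase Ckm was at 11.3 to 69.3 CPM in the vehicle libraries, at 93.9 CPM in oxaliplatin replicate 1 and at 0.530 to 2.49 CPM in the other 4 oxaliplatin libraries. Erythroid genes had 0 of 9, and 0 adjusted over the list alone (camera adjusted p = 0.0204, and adjusted p = 0.495 with an estimated correlation). Their mean log2 CPM was highest in oxaliplatin replicate 3 (5.69, against 4.08 to 5.05 after vehicle). The camera call was lost without oxaliplatin replicate 2 (0.114) or 4 (0.0811) or vehicle replicate 3 (0.0516) or 5 (0.0539) and with 1 surrogate variable (0.0702). Bone and cartilage markers had 0 of 8 (1 lower adjusted over the list alone, camera adjusted p = 0.315). Spinal cord markers had 0 of 8 (3 higher adjusted over the list alone, camera adjusted p = 0.15). These passed as a list, on the higher side, without oxaliplatin replicate 1 (0.0444) or 3 (0.0424) or vehicle replicate 4 (0.0367). Of 7 nuclear-retained RNAs 2 rose, Neat1 (0.33 ± 0.07) and Meg3 (0.32 ± 0.08), and 5 were higher adjusted over the list alone (camera adjusted p = 1.84e-05, and adjusted p = 0.15 with an estimated correlation). These 2 reached edgeR adjusted p values of 0.0871 and 0.144 when 1 library was left out. Replication-dependent histones, whose copies are nearly alike, had 1 of 25 lower, Hist1h2be (-0.61 ± 0.15, edgeR adjusted p = 0.0464, up to 0.146 when 1 library was left out). A total of 5 were lower adjusted over the list alone. The histone list had a camera adjusted p of 0.0135 (adjusted p = 0.479 with an estimated correlation) and of 0.0877 without vehicle replicate 5, 0.103 with 1 surrogate variable and 0.157 without vehicle replicate 5 and oxaliplatin replicate 1. In all, 10 of the 47 lists were called higher and 13 lower by camera.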

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

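In this part the tests of muscle or fat in vehicle replicate 5 and of single lists over other splits were chosen after the results were seen. Values that lay far from the other 4 libraries of their group were found in 17 of 258 groups checked, where chance gives about 12.9, so the number of such values is close to what chance brings. The total does not judge single libraries. Several of these values fell in oxaliplatin replicate 2, each on the vehicle side of its group. Without that library 343 genes were higher and 251 lower.

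In oxaliplatin replicate 2 the log2 CPM values were 2.5 for Etnppl (others 4.07 to 4.39), 2.21 for Cox4i2 (2.83 to 3.03), 8.51 for Sqle (8.24 to 8.27), 8.12 for Kcnd1 (7.88 to 7.94), 7.37 for P2rx3 (7.10 to 7.17), 4.55 for Cxcl12 (4.68 to 4.72) and 7.13 for the mean of the heat shock list (6.80 to 6.89), each on the vehicle side of its group. In oxaliplatin replicate 1 they were 8.83 for Cfd (3.32 to 4.88), 7.09 for Nsdhl (7.21 to 7.25), 5.22 for the mean of the adipocyte list (0.99 to 2.20) and 4.99 for the skeletal muscle list (-0.19 to 0.87). Pf4 was at 3.65 in oxaliplatin replicate 5 (3.21 to 3.32), and Plin4 at -1.33 in vehicle replicate 1 (0.12 to 0.56). In vehicle replicate 5, Cdkn1a was at 7.43 (6.64 to 6.77), the peptidergic nociceptor list at 5.55 (5.28 to 5.35) and the cold-sensing neuron list at 1.61 (2.01 to 2.17).

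Vehicle replicate 5 also had the highest mean of the nerve injury list, 5.75 in log2 CPM against 3.66 to 4.24 in the other vehicle libraries and 3.10 to 3.75 after oxaliplatin; Sprr1a, Atf3, Bdnf and the neuropeptide Gal stood at 189, 176, 129 and 721 CPM there. Muscle or fat in the sample is argued against: the nearer of these 2 scores, that of adipocytes, lay below the highest of the other vehicle libraries, at a difference of -1.36 against an SD of 0.72, and the muscle score was 2.04 against 2.93 to 4.24. For a response to dissection, the immediate early score without Atf3 and Jun was 3.57 in vehicle replicate 5. The rule set beforehand took a score inside the range of the other vehicle libraries, 2.79 to 3.60, to speak against it. The score lay inside, but differed from the highest of them by -0.0314, less than their SD of 0.34. A condition on the SD was not in that rule, and with it a response to dissection stays open. No biological explanation was tested, since the labels give nothing that sets this library apart.

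Splits of the 10 libraries other than the real one were used to ask whether chance could give as many calls. Of 100 splits into 5 and 5, drawn from 126, only the real one gave as many as 234 higher genes or 142 lower genes. The highest other count was 74, with each split taken at the larger of its 2 directions. A share of 1 in 100 is the smallest that these splits can give. Splits that mix the groups count a real difference as spread within them, which lowers their calls. Both real counts were thus the largest among these splits, but the splits cannot say how unlikely they are by chance, which is not excluded. For lists chance could give as many: 37 of 100 splits gave as many as the 10 higher lists (highest other 16), and 18 gave as many as the 13 lower lists (highest other 16). List by list, as small a camera p arose in 1 of 100 splits for p53 targets and for neurofilaments and tubulins, 2 for glucocorticoid targets and for heat shock genes, 3 for cholesterol synthesis and for crosslink and excision repair, 4 for endothelium and pericytes and for nuclear-retained RNAs, and 5 for proliferation. Among the other lists that camera called, it arose in 11 for lymphocytes, 13 for histones, 15 for skeletal muscle, 16 for complement, 18 for nerve injury genes, 20 for myelinating Schwann cells, 23 for macrophages and 24 for fibroblasts. The largest shares were 32 for nuclear respiratory chain genes, for immediate early genes and for erythroid cells, 33 for mitochondrial genome transcripts, 37 for extracellular matrix and 62 for ribosomal proteins.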

How the results depend on the processing

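Against 234 higher and 142 lower genes, DESeq2 called 514 and 408, limma voom with quality weights 439 and 342, the Schwann cell covariate 423 and 412, an adjusted p threshold of 0.1 424 and 304, and the fit without oxaliplatin replicate 1 and vehicle replicate 5, chosen after seeing the data, 142 and 76; leaving out 1 library gave 79 to 343 and 34 to 251. DESeq2 shared 376 calls with the 376 of edgeR. RLE factors, both filters, no composition factor and 1 surrogate variable stayed within 1.5 times. Txnip had a log2 fold change of 1.13 in DESeq2, 1.23 in limma voom and 1.14 at the looser threshold, past it in each, and 1.02 to 1.31 when 1 library was left out; it stayed above 0 in every alternative. Lists called higher and lower (10 and 13) were 1 and 0 with an estimated correlation and 5 and 3 with fry, which does not compare a list with other genes, 9 and 9 with 1 surrogate variable (17 of the 23 calls shared), 10 and 10 (18 shared) without oxaliplatin replicate 1 and vehicle replicate 5, and ranged over 10 to 12 and 9 to 16 when 1 library was left out. Of 68 called genes examined, 0 reversed, 601 of 675 alternative fits and 483 of 680 fits without 1 library still called them, and 30 kept the call whichever library was left out; 35 of 68 did without oxaliplatin replicate 4, 36 without vehicle replicate 4 and 39 without oxaliplatin replicate 5. Fewer libraries leave fewer degrees of freedom; otherwise the cause was not tested. With the replicate number as a block, 382 genes were higher and 278 lower, and of the list calls adipocytes (camera adjusted p = 7.60e-04), metallothioneins (0.0241) and antioxidant genes (0.0241) were gained and erythroid cells (0.065) lost. Same-numbered libraries correlated at -0.04 to 0.21, with 2 pairs over 0.1, and 6 of 10 libraries correlated best with their own number. These values leave open whether the numbers pair the libraries, and the main fit did not pair them. At 52963470 counts or more per library, Nlrp3 and Il1b fell below the filter on low counts, and lower depths were not tried.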

Other observations

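In this part the 7 added gene lists, the tests of a shared glucocorticoid signal, of fat tissue, of fewer leukocytes and of fewer dendritic cells were chosen after the results were seen; the genes named from the added lists were named after their values were seen, so the p-values of these lists are not independent evidence. Markers of tissue macrophages that sit along vessels and carry Lyve1 were higher after oxaliplatin: of 11 tested members 5 rose, 7 adjusted over the list alone, at a median log2 fold change of 0.54 (camera adjusted p = 1.22e-07; adjusted p = 0.0505 with an estimated correlation). Mertk, a receptor for the uptake of dead cells, rose 1.84-fold (0.88 ± 0.12) and its ligand Gas6 by 0.38 ± 0.07 on the log2 scale, and both kept their calls whichever library was left out. Mertk and Gas6 are also made by other DRG cells. Folr2 rose by 1.44 ± 0.29, F13a1 by 0.96 ± 0.19 and Pf4 by 0.69 ± 0.17, with edgeR adjusted p values up to 0.062, 0.0751 and 0.138 when 1 library was left out, and Lyve1 was at 0.64 ± 0.16 (edgeR adjusted p = 0.0526).

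Of 8 MHC class II genes, listed after the falls of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 were seen, those 4 were lower, over all genes and adjusted over the list alone, and the other 4 were at -0.44 to -0.18, so no list test is given. Class I genes had 0 of 11 past the threshold (median -0.02, camera adjusted p = 0.786). Dendritic cell markers had 3 of 11 lower, Cd209a (-2.11 ± 0.40), Slamf7 (-2.99 ± 0.60) and Irf8 (-1.16 ± 0.24), none above 2.36 CPM in mean, with 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.00102; adjusted p = 0.0505 with an estimated correlation). Slamf7 and Irf8 reached edgeR adjusted p values of 0.0555 and 0.0729 when 1 library was left out. The core macrophage list left out genes already called, so its 0 of 14 past the threshold was set by that choice. Its median (-0.12, camera adjusted p = 0.393) is drawn towards 0 by the same choice and does not show that macrophages were unchanged. Pan-neuronal genes had 0 of 14 past the threshold (2 lower adjusted over the list alone, camera adjusted p = 0.121). Genes that rise in fasting had 1 of 14 higher, Pdk4, and 3 adjusted over the list alone (camera adjusted p = 0.00290; adjusted p = 0.0746 with an estimated correlation).

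For the fall of class II genes, more blood left in the vehicle ganglia was tested with the haemoglobin level as a covariate. The class II median was -1.24 with it and -1.12 without it, so this level did not account for the fall. The rule set beforehand took a median below -0.562 by more than the median SE of single genes (0.27) to speak against blood. That rule was met. Resampling the 8 genes gave the median without the covariate an SE of 0.69, which measures the spread between genes. Erythroid means were 4.41 and 5.69 in oxaliplatin replicates 1 and 3, 1.84 to 3.78 in the others and 4.08 to 5.05 after vehicle. H2-Aa, H2-Ab1, H2-Eb1 and Cd74 were lower in all 5 oxaliplatin libraries than in any vehicle library. These values argue against blood as the whole cause for these genes, and a part played by it is not excluded. An equal loss of every kind of leukocyte as the whole cause would lower their markers alike. The Lyve1-type list had a median of 0.54 ± 0.16 (SE), or 0.54 ± 0.18 without Mertk and Gas6, 0.97 ± 0.25 above that of the macrophage list. It was picked with values in view and shares Lyve1 with the macrophage list, and these SEs come from resampling genes, not animals. The values show that most of these picked markers did not fall, and they cannot decide on the cause. Fewer leukocytes of some kinds cannot be told apart from other causes, and a change within the Lyve1-type cells stays open too, since the macrophage list had a median of -0.431 ± 0.20, within its error of 0.5 times the class II median (-0.562), and the lymphocyte list one of -0.58. Fewer dendritic cells cannot be told apart from lower class II transcription in cells that stayed: the 11 dendritic markers had a median of -0.52 ± 0.48 and went both ways, and the test first set, on the markers that had not passed, left out those that fell and is not used. An effect of oxaliplatin on antigen-presenting cells is therefore a hypothesis that stays open, as is any other difference between the treated and untreated mice.

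Txnip and glucocorticoid targets were both higher after oxaliplatin, and a candidate explanation is a shared glucocorticoid signal, for instance from stress of the treated mice. Within groups, libraries with more Txnip had a higher mean of the glucocorticoid list (deviations from the group means over 10 libraries, Pearson r = 0.751, exact permutation p = 0.0268, adjusted p = 0.0804 over 3 relations; Spearman rho = 0.685, exact p = 0.0657, adjusted p = 0.197), an r above that of 98.6% of tested genes with this list, but without the 2 farthest libraries, oxaliplatin replicate 2 and vehicle replicate 1, r was 0.432 (exact permutation p = 0.351), above 0 and no longer past 0.05 over 8 libraries. The same measure was -0.067 in Pearson r and -0.067 in rho for the p53 list (exact permutation p = 0.868 and 0.917, adjusted 0.868 and 0.917; r = -0.166 without its 2 farthest) and 0.314 and 0.285 for the adipocyte list (exact permutation p = 0.499 and 0.394, adjusted 0.749 and 0.592; r = -0.164 without its 2 farthest). Fat in the sample as the whole cause is argued against, since without oxaliplatin replicate 1, the library with the most adipocyte RNA, the Txnip log2 fold change was 1.12 ± 0.30 and the median of the glucocorticoid list 0.84 ± 0.11. A different time of day at collection cannot be told apart from the treatment, since clock genes that peak at opposite times differed by 0.34 ± 0.19 in mean log2 fold change, between the bounds set beforehand, and the hour of collection is not given in the sources used here.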
